A study of Mus musculus with 12 samples.

How the data were processed

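RNA of 12 cultures of mouse bone marrow-derived macrophages was measured on Affymetrix whole-transcript gene arrays, 3 arrays in each of 4 groups. The groups were Hdac3 +/- cells, labelled wild type, and Hdac3 -/- cells, each untreated or given 100 ng/ml of LPS for 4 h on the 7th day of culture. RNA was prepared with RNeasy columns and DNase I, and the labelled cDNA with the Ambion WT Expression kit and the Affymetrix GeneChip WT terminal labelling kit. The deposited values are log2 signals per probe set, which the authors normalized across arrays and summarised by RMA with the affy package, per the submitters' processing notes. The versions, the settings, the chip description file and the genome build are not given in the sources used here. The scale was checked on the values, whose median lay between 5.19 and 5.37 on every array. The interquartile range was 3.70, 3.52 and 3.80 in the untreated and 3.49, 3.19 and 3.20 in the LPS-treated Hdac3 +/- arrays, and 3.74, 3.66 and 3.59 in the untreated and 3.50, 3.39 and 3.70 in the LPS-treated Hdac3 -/- arrays. The number of arrays limits the precision.

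The table held 28193 probe sets and 12 arrays, and no array was left out. Gene names came from the platform's annotation table. It gave 1 symbol to 21648 probe sets, several to 1313 and none to 5232. The last 2 kinds were left out of the tests of genes, because they belong to no single gene. Of the probe sets with 1 symbol 21553 were matched by Entrez identifier to a RefSeq gene table of assembly GRCm38.p6, which was used only for names and for the order of genes along the chromosome, and 0 symbols had to be updated. That table gives Cxcl11, Mx1 and Mx2 as transcribed pseudogenes. For the 954 genes with more than 1 probe set the one with the highest mean signal was used, which gave 19945 genes.

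The values were analysed with limma 3.58.1 in R 4.3.3, with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6 for tables and matplotlib 3.10.9 for figures. A linear model with a mean for each of the 4 groups was fitted to all 12 arrays, with moderated t-statistics from eBayes without a trend. The 5 contrasts were LPS against untreated in each genotype, Hdac3 -/- against +/- untreated and after LPS, and the difference of both LPS responses (the interaction of genotype and LPS). P-values were adjusted by the Benjamini-Hochberg method over 19945 genes for each contrast, and genes with an adjusted p under 0.05 were counted as changed. Principal components 1 to 4 of the arrays held 51.1%, 19.7%, 8.1% and 4.83% of the variance. Genes induced or repressed on average were those whose mean LPS response over both genotypes passed the same threshold with a change of at least 2-fold. Each was then sorted by the interaction test. Overlaps of called genes were set against the number for independent lists, and effects were correlated by the Pearson and Spearman methods. Only contrasts that share no arrays were compared in this way.

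Gene lists were written from general knowledge before the data were examined. There were 20 lists of pathways and functions and 12 lists of markers of other cell types or of sex, with 509 entries, of which 459 were measured. A list was tested against all other genes with camera of limma at its preset inter-gene correlation of 0.01, adjusted by the Benjamini-Hochberg method over all lists of a contrast. Camera with an estimated correlation and the rotation test fry, which asks whether the members move together without reference to other genes, were run beside it. Camera compares the mean test statistic of the members with that of all other genes. A list can therefore shift without any member past the threshold, and a few members with large statistics can carry it. List members were also counted after adjusting over the list alone. Some genes stand in more than 1 list, such as Irf7 and Usp18.

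Genes to be named were fixed by a rule before the data were examined. Hdac3 came first. The rule then took up to 10 genes in each direction with the largest change among those past the threshold whose groups did not overlap, skipping predicted genes and clone names. For the interaction, each sign had to hold with every array left out. For each list it took up to 4 members past the threshold with the largest change, or the 2 with the smallest p where none passed. Of 7 genes to be named in any case, 2 had no row used here and were not analysed here. Genes beyond this rule, among them further members that complete a count of 5 or fewer, such as Irf3, Hdac1 and Tbl1x, were chosen after their values were seen.

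The replicate numbers were checked as a possible pairing. Deviations of each array from its group mean were correlated across genes between arrays of different groups. In Hdac3 +/- arrays the untreated and the LPS-treated array of a number correlated at 0.243, 0.327 and 0.223, and replicate 1 was male in both, so the numbers may pair these arrays. Values as large also arose between arrays that share neither number nor genotype, such as 0.514 for +/- untreated 2 with -/- untreated 3, 0.358 for +/- untreated 1 with -/- untreated 2 and 0.332 for +/- LPS 1 with -/- LPS 3. In Hdac3 -/- arrays the correlations were 0.0898, 0.195 and -0.122, and between the genotypes 0.0584, -0.472 and -0.148 untreated and -0.169, -0.0853 and -0.341 after LPS, so there the numbers show no pairing. The groups were therefore fitted without pairing, and fits with the replicate number as a block were run as alternatives.

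The alternatives chosen before the data were examined left out genes whose highest group mean lay in the lowest 33.3%, tested all probe sets, averaged the probe sets of a gene, centred each array on its median, applied cyclic loess, used eBayes with a trend and robust variances, weighted arrays, used the replicate number as a block, fitted only the 6 arrays compared, asked for a 2-fold change as well, used an adjusted p under 0.01 and left out each array in turn. Induced genes were also chosen on each genotype alone. Quantile normalization, a fit without both male arrays and a fit with a replicate block for each genotype were added after the data were seen. Genotype contrasts cannot be estimated in the last fit, nor the interaction from 6 arrays.

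The model was tested on simulated data of 19945 genes in groups of 3 arrays. Of 50 genes changed by a log2 of 1 limma found 80%, 80%, 66%, 82% and 46% in the 5 contrasts in the order above, and of 50 genes changed by 2 it found 92%, 98%, 98%, 96% and 90%. Unchanged genes made up between 4.67% and 7.69% of the calls. Camera found 20 of 20 simulated lists of 25 genes shifted by 0.5 and called 0 unshifted lists at an unadjusted p under 0.05. Real data hold correlated genes, which the simulation does not.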

Results

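Gene expression was measured on single-colour microarrays in 12 cultures of mouse bone marrow-derived macrophages. The cells were grown from C57BL/6 marrow with L929-conditioned medium, a source of the macrophage growth factor CSF1. They fell into 4 groups of 3 arrays: Hdac3 +/- cells, which the submitters label wild type, and Hdac3 -/- cells, each left untreated or given 100 ng/ml of lipopolysaccharide (LPS, a bacterial cell wall component sensed by TLR4) for 4 h. Each array gave a log2 signal for 28193 probe sets, and 19945 genes were tested. The median log2 signal per array lay between 5.19 and 5.37, and the number of arrays limits the precision of every value. Nothing in the labels says that the replicates of a group came from separate animals, so the p-values measure only the spread between these arrays. Log2 differences are given ± 1 SE of the limma model, with n = 3 arrays per group throughout, and an array is named by genotype, treatment and replicate number, as in +/- LPS 1.

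Hdac3, the histone deacetylase that acts in the NCoR/SMRT corepressor complex, was lower in every Hdac3 -/- array than in any Hdac3 +/- array. Its log2 signal was 9.42, 9.10 and 8.98 in the untreated and 8.90, 9.02 and 8.66 in the LPS-treated Hdac3 +/- arrays. It was 7.39, 7.52 and 7.39 in the untreated and 6.91, 7.25 and 7.18 in the LPS-treated Hdac3 -/- arrays. The difference for Hdac3 was -1.74 ± 0.153 without LPS (adjusted p = 1.66e-05) and -1.75 ± 0.153 with it (adjusted p = 5.9e-06). The values come from a single probe set (10458461). The position of the deleted part is not given in the sources used here, and a probe outside that part checks nothing. The list of 14 histone deacetylases and NCoR/SMRT complex members, Hdac3 included, had not shifted between the genotypes (adjusted p = 0.896 untreated and 0.367 after LPS). After LPS, Hdac1 was lower in Hdac3 -/- arrays (-0.91 ± 0.147), and the complex members Tbl1x, Gps2 and Tbl1xr1 were higher by 0.71, 0.65 and 0.53.

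**Figure D1:**
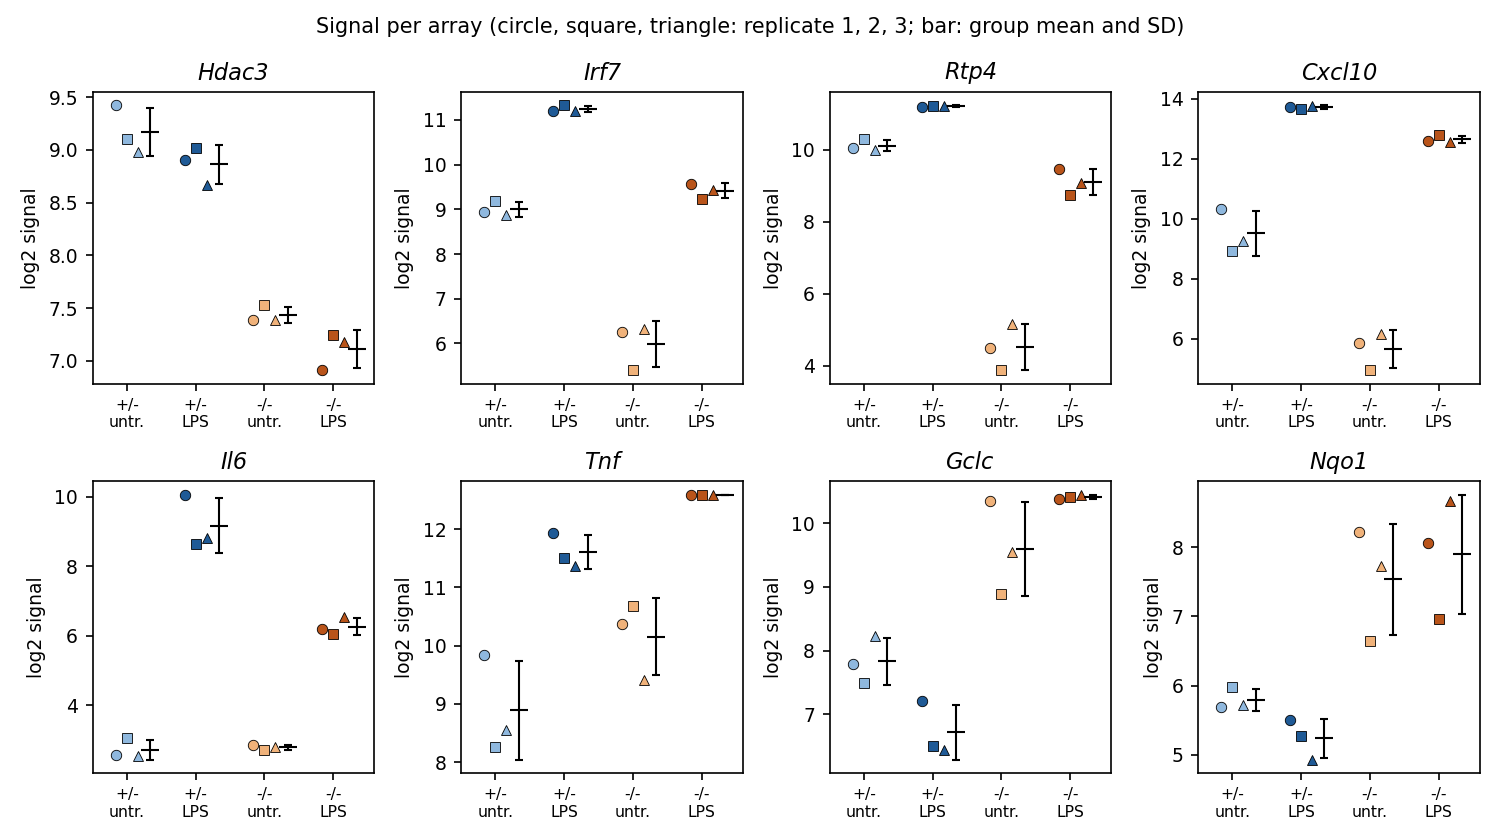
Log2 signal of 8 genes on each of the 12 arrays, with 1 point per array and the mean and SD of each group of 3. The mean of Il6 was 6.26 in the LPS-treated Hdac3 -/- arrays and 9.17 in the LPS-treated Hdac3 +/- arrays.

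The LPS response of Hdac3 +/- macrophages gave the inflammatory program of cells that kept an Hdac3 allele. Ptgs2, the inducible cyclooxygenase, rose 162-fold (log2 7.34 ± 0.400, adjusted p = 4.26e-08). The cytokines Il1a (log2 7.18), Il1b (6.57) and Il6 (6.44 ± 0.291; probe set 10520452) and the nitric oxide synthase Nos2 (6.70 ± 0.377) rose as well. So did the collagenase Mmp13 (6.63), Ifi205 (6.62), the endothelin precursor Edn1 (6.21), Cd69 (5.86) and the GTPase Gbp5 (5.74). The stress-response gene Sesn1 fell by 5.07 (SE 0.251, adjusted p = 1.99e-08), the chemokine receptor Cxcr4 by 4.34 and the Ras activator Rasgrp3 by 3.97. Ints6l, Otulinl, Tmem273, Klhl6, the cannabinoid receptor Cnr2, the checkpoint kinase Chek2 and Rab3il1 fell too, with log2 values between -3.63 and -3.22. Tnf rose by 2.72 ± 0.364 (adjusted p = 0.000109) and Arg1 by 2.32 ± 0.787 (adjusted p = 0.045). The type I interferon gene Ifnb1 had a mean log2 signal of 3.85 without and 3.95 with LPS (adjusted p = 0.762), and of 3.90 and 3.85 in the Hdac3 -/- groups.

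All 34 measured interferon-stimulated genes rose in Hdac3 +/- arrays (34 adjusted over the list alone), led by Gbp5, Mx1 (4.59), Cmpk2 (4.49) and Ifit1 (4.48). Their median was 2.57 (adjusted p = 5.05e-34, and adjusted p = 0.0553 with an estimated correlation). Of 30 primary response genes, the NF-kB targets and immediate early genes, 25 rose (26 adjusted over the list alone). The list passed at adjusted p = 5.21e-19, and had adjusted p = 0.0553 with an estimated correlation. Of 22 secondary response genes, the later cytokines and effectors, 17 rose (19 adjusted over the list alone), with adjusted p = 1.49e-14, and adjusted p = 0.0553 with an estimated correlation. In type I interferon signalling 8 of 17 genes rose, among them Usp18 (3.36), Socs1 (2.70) and Irf7 (2.25), and Irf3 fell by 0.74 (10 and 2 adjusted over the list alone). That list had adjusted p = 0.000456, and adjusted p = 0.123 with an estimated correlation. Of 18 genes of glycolysis and the hypoxia response 11 rose (12 adjusted over the list alone), with the glycolytic regulator Pfkfb3 at 3.65 and the glucose transporter Slc2a1 at 2.11 (adjusted p = 7.01e-05, and adjusted p = 0.119 with an estimated correlation). Of 11 genes of MHC class I presentation 9 rose (9 adjusted over the list alone), with the peptide transporter Tap1 at 1.70 (adjusted p = 3.43e-05, and adjusted p = 0.107 with an estimated correlation). The class I heavy chain genes of that list, H2-K1, H2-D1 and H2-T23, had no row used here. Of 15 matrix remodelling genes 6 rose and 1 fell (7 and 1 adjusted over the list alone), with Mmp13 at 6.63 and Timp1 at 5.59 (adjusted p = 0.00752, and adjusted p = 0.107 with an estimated correlation).

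Of 20 genes of cholesterol synthesis and uptake 10 fell in Hdac3 +/- arrays (12 adjusted over the list alone), with Dhcr7 at -1.77 and Lss at -1.73. Their median was -0.67 (adjusted p = 5e-06, and adjusted p = 0.254 with an estimated correlation). Of 33 cell cycle genes 16 fell (18 adjusted over the list alone), with a median of -1.18 (adjusted p = 1.53e-07, and adjusted p = 0.479 with an estimated correlation). Of the 14 histone deacetylases and complex members 7 fell (8 adjusted over the list alone), led by Tbl1xr1 (-1.44) and Hdac5 (-1.32), and Hdac1 rose by 0.78. That list had adjusted p = 0.00459, and adjusted p = 0.0726 with an estimated correlation. Of 17 lysosomal genes 5 fell (6 adjusted over the list alone), with the lysosomal regulator Tfeb at -1.38 (adjusted p = 0.00697, and adjusted p = 0.45 with an estimated correlation). Markers of eosinophils, another blood cell, passed too (median 0.42). Of 6 such markers Ccr3 (1.97), Prg3 (0.45) and Il5ra (0.42) rose, or 5 adjusted over the list alone. The list had adjusted p = 0.0232, and adjusted p = 0.254 with an estimated correlation. The other marker lists had positive medians as well, from 0.04 (neutrophil) to 0.34 (dendritic cell). The lower quartile of all probe sets was 3.76, 3.84 and 3.70 in untreated and 3.84, 3.99 and 3.95 in LPS-treated Hdac3 +/- arrays. Small rises of dim markers are therefore not told apart from a general rise of low signals.

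Other lists did not pass as a whole in Hdac3 +/- arrays. In alternative activation 6 of 22 genes rose and 1 fell (adjusted p = 0.106), in prostanoid metabolism 3 of 17 rose and 6 fell (adjusted p = 0.878), and among p53 targets 3 of 17 rose and 8 fell (adjusted p = 0.0828). In LPS sensing 7 of 17 genes rose, with the adaptor Myd88 at 1.33, and 3 fell, with the receptor Tlr4 at -1.16 (adjusted p = 0.12). Among NRF2 targets 3 of 14 rose and 2 fell (adjusted p = 0.864), among heat shock genes 2 of 9 rose and 1 fell (adjusted p = 0.881), and among macrophage identity genes 3 of 13 rose and 4 fell (adjusted p = 0.383). LXR and PPAR lipid handling had 2 of 19 genes up and 4 down (adjusted p = 0.133), and MHC class II presentation 1 of 8 up (adjusted p = 0.172). With the arrays paired by replicate number within each genotype both passed, at adjusted p = 0.0192 (alternatives 0.0192 to 0.496) and adjusted p = 0.0266 (0.0266 to 0.421).

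In all, 4997 of 19945 genes changed with LPS in Hdac3 +/- arrays, 1912 up and 3085 down, and 1792 of them by at least 2-fold. Calls were lost for lysosome in 2 of 22 alternatives (adjusted p 0.000912 to 0.0794), for the deacetylases in 1 (0.00283 to 0.0581) and for the eosinophil markers in 3 (0.0122 to 0.0641), among them without +/- LPS 3 (0.0547). Calls were gained for LPS sensing in 5 of 22 (0.00209 to 0.436), among them without +/- untreated 3 (0.0494) and +/- LPS 2 (0.0469), for alternative activation with dim genes left out (0.0266; 0.0266 to 0.253), for p53 targets with array weights (0.0443) and without +/- untreated 2 (0.0367; 0.0367 to 0.204), for MHC class II without +/- LPS 1 (0.0464) and for dendritic cell markers with array weights (0.0491) and without +/- LPS 2 (0.0353; 0.0353 to 0.487).

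Hdac3 -/- macrophages also responded to LPS. The interleukins Il1a (7.35 ± 0.278, adjusted p = 3.06e-09) and Il1b (6.88) and the chemokines Cxcl10 (6.99 ± 0.324), Ccl5 (6.38) and Cxcl3 (5.67) were among the 10 named genes that rose the most. The others were the antiviral genes Ifit1 (5.97), Rsad2 (5.66) and Cmpk2 (5.26), the cholesterol hydroxylase Ch25h (5.42) and Ptgs2 (5.41). Tnf rose by 2.43 ± 0.364 (adjusted p = 0.000691), and Arg1 was at 1.72 (adjusted p = 0.239). Rasgrp3 (-3.85), the G protein regulator Rgs2 (-3.54), Sesn1 (-3.52) and Slco4a1 (-3.23) fell the most, with Rab3il1, Otulinl, Gpr65, Abcd2, Klhl6 and the phagocytic receptor Mertk at log2 values between -2.94 and -2.61.

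Of the interferon-stimulated genes 33 of 34 rose in Hdac3 -/- arrays (33 adjusted over the list alone), with a median of 2.75. Of the primary response genes 25 of 30 rose (27 adjusted over the list alone), and of the secondary response genes 14 of 22 (15 adjusted over the list alone), with Il12b at 5.22 and Nos2 at 4.30. These 3 lists passed at adjusted p = 2.06e-65, 5.87e-33 and 1.82e-21, and at adjusted p = 0.0107 each with an estimated correlation. In glycolysis and hypoxia 10 of 18 genes rose (14 adjusted over the list alone; adjusted p = 5.23e-12, and adjusted p = 0.0153 with an estimated correlation). Of the 14 deacetylases and complex members 2 fell, Hdac5 (-1.08) and Tbl1xr1 (-0.99) (5 adjusted over the list alone; adjusted p = 0.00288, and adjusted p = 0.0495 with an estimated correlation). Cholesterol synthesis and uptake had 6 of 20 genes down (12 adjusted over the list alone; adjusted p = 7e-09, and adjusted p = 0.188 with an estimated correlation). The cell cycle had 4 of 33 down (4 adjusted over the list alone; adjusted p = 4.06e-06, and adjusted p = 0.542 with an estimated correlation).

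Type I interferon signalling had 6 of 17 genes up in Hdac3 -/- arrays (7 adjusted over the list alone; adjusted p = 3.48e-06, and adjusted p = 0.0519 with an estimated correlation). MHC class I presentation had 3 of 11 up (4 adjusted over the list alone; adjusted p = 0.000159, and adjusted p = 0.119 with an estimated correlation). Matrix remodelling had 3 of 15 up and 1 down (8 and 1 adjusted over the list alone; adjusted p = 0.00288, and adjusted p = 0.0559 with an estimated correlation). The lysosome had 1 of 17 down (1 adjusted over the list alone; adjusted p = 0.00485, and adjusted p = 0.466 with an estimated correlation). NRF2 targets shifted up, with Slc7a11 (3.50), Srxn1 (1.08) and Txnrd1 (0.98) past the test (3 adjusted over the list alone; adjusted p = 0.00472, and adjusted p = 0.426 with an estimated correlation). LXR and PPAR lipid handling shifted down, with 4 of 19 genes lower, among them the cholesterol exporter Abcg1 (-1.98), and Hilpda higher by 2.40 (1 up and 4 down adjusted over the list alone; adjusted p = 0.0355, and adjusted p = 0.379 with an estimated correlation). In LPS sensing Tlr4 fell by 1.56, and the list did not pass (adjusted p = 0.122), but it did in 2 of 22 alternatives (0.0176 to 0.252), after cyclic loess (0.0176) and quantile normalization (0.0374). None of the 12 marker lists passed the camera test of limma in Hdac3 -/- arrays (lowest adjusted p = 0.187).

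In all, 1769 genes changed with LPS in Hdac3 -/- arrays, 736 up and 1033 down, and 769 of them by at least 2-fold. The count was 4424 with array weights, 1129 without -/- LPS 1 and 1143 without -/- untreated 1, and the NRF2 call was lost in 3 of 22 alternatives (adjusted p 1.77e-05 to 0.158), among them without -/- untreated 2 (0.0594) and -/- LPS 3 (0.0671). The LXR and PPAR call was lost in 8 of 22 (0.000956 to 0.152), among them without +/- LPS 2 (0.0608), -/- untreated 1 (0.104), -/- untreated 3 (0.0822) and -/- LPS 2 (0.152).

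The LPS effects in both genotypes, which share no arrays but use the same estimate of each gene's spread, overlapped. Of the genes that rose in Hdac3 +/- arrays 593 also rose in Hdac3 -/- arrays, against 70.56 for independent lists, and 881 fell in both, against 159.8. Only 5 and 3 genes were called in opposite directions, against 99.03 and 113.8. The effects correlated at r = 0.796 (rho = 0.637) across genes, which are not independent replicates.

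Untreated Hdac3 -/- and +/- macrophages were compared for what loss of Hdac3 changed before any stimulus. Rtp4, an interferon-induced gene, was 48.3-fold lower in Hdac3 -/- arrays (log2 -5.60 ± 0.258, adjusted p = 1.17e-07; probe set 10434778). Ifit3 (-4.40 ± 0.332), the chemokine Cxcl10 (-3.85 ± 0.324), Oasl2 (-3.80 ± 0.301), Samd9l (-3.79), Ifi209 (-3.66), the ISG15 protease Usp18 (-3.54) and Ifit1 (-3.52) were also lower, and so were Fcrls (-3.68) and Fgl2 (-3.55). Of the 34 interferon-stimulated genes 30 fell (32 adjusted over the list alone), with a median of -2.35 (adjusted p = 7.1e-82, and adjusted p = 0.0079 with an estimated correlation). The 4 that did not pass over all genes, named after their values were seen, were Isg20 (-0.67), Daxx (-0.60), Cxcl9 (-0.31) and Cxcl11 (-0.05). In type I interferon signalling 4 of 17 genes fell (5 adjusted over the list alone), Usp18 and the transcription factors Irf7 (-3.00), Stat2 (-1.80) and Irf9 (-0.97). The list had adjusted p = 0.00118, and adjusted p = 0.224 with an estimated correlation.

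Targets of NRF2, the transcription factor of the antioxidant response, were higher in untreated Hdac3 -/- arrays. Of 14 measured 12 rose (12 adjusted over the list alone), led by the cystine transporter Slc7a11 (2.85 ± 0.520, adjusted p = 0.00789), the glutathione synthesis enzyme Gclc (1.76 ± 0.310), the quinone reductase Nqo1 (1.74 ± 0.399) and the glutathione reductase Gsr (1.74 ± 0.215). Their median was 1.26 (adjusted p = 3.48e-20, and adjusted p = 0.0283 with an estimated correlation). The LPS-binding protein gene Lbp rose the most of all genes (3.39 ± 0.281, 10.5-fold, adjusted p = 9.59e-06). The glutathione transferases Gsta3 (3.03) and Gstp1 (2.60), the chemokine receptor Ccr1 (3.02), the phagocytic bridging protein Mfge8 (2.97) and the elastase Mmp12 (2.91) were also higher, with Il1rl2 (2.58), Akr1c18 (2.51) and the chemokine Ccl6 (2.50). In LXR and PPAR lipid handling 3 of 19 genes rose, the lipid carriers Fabp4 (2.28) and Apoe (1.22) and the lipid droplet protein Plin2 (1.45). That list (4 up and 1 down adjusted over the list alone) had adjusted p = 0.0184, and adjusted p = 0.449 with an estimated correlation. In matrix remodelling Mmp12, Plaur (2.19) and Mmp13 (1.31) rose and Mmp14 fell by 0.94 (5 up and 1 down adjusted over the list alone; adjusted p = 0.00797, and adjusted p = 0.132 with an estimated correlation).

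Antigen presentation lists were lower in untreated Hdac3 -/- arrays. In MHC class I presentation Tap1 (-1.42 ± 0.155) and the immunoproteasome subunits Psmb9 (-1.18) and Psmb8 (-0.72) fell, 3 of 11 genes (10 adjusted over the list alone). The list had adjusted p = 2.58e-10, and adjusted p = 0.0283 with an estimated correlation. It held no measured class I heavy chain gene, so it does not tell whether those genes were lower. Its member Nlrc5, named after its values were seen, entered with the brightest of 19 probe sets (0.14), which was not called, whereas 16 of the 19 were called lower. In MHC class II presentation 0 of 8 genes passed limma over all genes and 5 were lower adjusted over the list alone, with H2-Aa at -2.30 (adjusted p = 0.0721). Its median was -0.74 (list adjusted p = 0.00587, and adjusted p = 0.449 with an estimated correlation). Lysosomal genes shifted up with 0 of 17 past limma over all genes and 3 adjusted over the list alone (median 0.25, adjusted p = 0.000427, and adjusted p = 0.449 with an estimated correlation).

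The inflammatory response lists had not shifted between the untreated genotypes. Of the primary response genes 1 of 30 rose (4 adjusted over the list alone), the NF-kB inhibitor Tnfaip3 (1.33 ± 0.201, adjusted p = 0.00198), with a list median of 0.10 (adjusted p = 0.461). Of the secondary response genes 0 of 22 passed limma (1 up and 2 down adjusted over the list alone; list adjusted p = 0.989). Tnf was at 1.27 ± 0.364 (adjusted p = 0.0963), Il6 at 0.06, Nos2 at -0.08 and Arg1 at 0.40, all short of the threshold. Of the macrophage identity genes Cx3cr1 (-2.02) and Fcgr1 (-1.45) fell and Cebpa (1.16) and Cebpb (1.12) rose, with no shift of the 13 as a list (adjusted p = 0.989). Prostanoid metabolism (Ptger2 1.98 and Alox5 -1.12; adjusted p = 0.23), alternative activation (Pparg -0.68; adjusted p = 0.644) and p53 targets (Pmaip1 -0.69; adjusted p = 0.283) each had 1 or 2 genes past the test and no list shift. Cholesterol synthesis (adjusted p = 0.461), glycolysis (0.806), LPS sensing (0.989) and heat shock (0.989) had not shifted either. None of the 12 marker lists passed the camera test of limma, with the lowest adjusted p at 0.0701 for neutrophil markers, of which Ngp fell by 1.18.

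In all, 531 genes differed between the untreated genotypes, 243 higher and 288 lower in Hdac3 -/- arrays, and 262 of them by at least 2-fold. The cell cycle list passed narrowly with 0 of 33 genes past limma (median -0.22, adjusted p = 0.049, and adjusted p = 0.946 with an estimated correlation). The count was 1186 with array weights, 266 without -/- untreated 1, and 321 with the 6 untreated arrays alone, and the cell cycle call was lost in 10 of 21 alternatives (adjusted p 1.44e-11 to 0.95) and its direction turned in 1 more, without -/- untreated 3 (median 0.02, 0.95). The single arrays behind lost calls were +/- untreated 1 (0.921), +/- untreated 3 (0.861), +/- LPS 1 (0.0538), +/- LPS 3 (0.0513), -/- LPS 1 (0.0505) and -/- LPS 2 (0.0524). The LXR and PPAR call was lost in 3 of 21 (0.000929 to 0.089), among them without -/- untreated 1 (0.089) and -/- untreated 3 (0.0564). Calls were gained for primary response genes without -/- untreated 2 (0.00189; 0.00189 to 0.966), for cholesterol synthesis with array weights (0.0174) and without +/- untreated 2 (0.00843) or -/- untreated 2 (0.00722; 0.00722 to 0.924) and for neutrophil markers with arrays centred on their median (0.0468) and without +/- untreated 3 (0.0329) or -/- untreated 3 (0.0327; 0.0327 to 0.347).

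After LPS, genes of the interferon response and several inflammatory effectors were lower in Hdac3 -/- than in +/- arrays. Ms4a4c was 53.3-fold lower (log2 -5.74 ± 0.280, adjusted p = 8.56e-08). The death ligand Tnfsf10 (-4.99 ± 0.254), the interferon-inducible GTPase Iigp1 (-4.74), Ifit3b (-4.67), Fcrls (-4.60) and Fgl2 (-4.55) followed, with the matrix glycoprotein Tnc (-4.31 ± 0.164), Ms4a6b (-4.13), the cytokine Il33 (-3.96) and the cyclin Ccnd2 (-3.91). Of the interferon-stimulated genes 33 of 34 were lower (34 adjusted over the list alone), with Cxcl11 at -3.48 and Ifit2 at -3.26. Their median was -1.97 (adjusted p = 2.64e-39, and adjusted p = 0.0592 with an estimated correlation). The exception over all genes, named after its value was seen, was Parp14 (-0.66, adjusted p = 0.0963). Of the secondary response genes 6 of 22 were lower (6 adjusted over the list alone), with Edn1 at -3.61 ± 0.278, Il6 at -2.91 ± 0.291 (adjusted p = 1.91e-05) and Nos2 at -2.49 ± 0.377, and the scavenger receptor Marco was higher by 2.93 ± 0.622. The list had adjusted p = 0.0283, and adjusted p = 0.527 with an estimated correlation. Of the primary response genes 4 of 30 were lower (4 adjusted over the list alone), among them Ptgs2 (-2.27 ± 0.400), Btg2 (-1.78) and Ccrl2 (-1.12), and Sqstm1 was higher by 1.45, with no shift of the list (adjusted p = 0.547). Tnf was at 0.98 ± 0.364 (adjusted p = 0.0888).

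MHC class I presentation was lower after LPS in 8 of 11 genes (10 adjusted over the list alone), with Tap1 at -1.79, Tap2 at -1.56, Psmb10 at -1.51 and Psmb9 at -1.46 (adjusted p = 3.14e-09, and adjusted p = 0.0592 with an estimated correlation). No class I heavy chain gene was among the 11. The probe set used for Nlrc5 was not called here either (-0.29), whereas 18 of its 19 were called lower. MHC class II presentation was lower in 4 of 8 genes (4 adjusted over the list alone), H2-Aa (-3.02), its chaperone Cd74 (-2.29), H2-Ab1 (-1.64) and H2-Eb1 (-1.21). That list had adjusted p = 0.0092, and adjusted p = 0.527 with an estimated correlation. In type I interferon signalling 7 of 17 genes were lower and 1 higher (8 and 1 adjusted over the list alone), with Usp18 at -2.27 and Irf7 at -1.83 (adjusted p = 0.0092, and adjusted p = 0.424 with an estimated correlation). Alternative activation had 3 of 22 genes lower (3 adjusted over the list alone), Tmem26 (-1.27), Flt1 (-1.25) and Ccl22 (-0.65), and Egr2 higher by 1.81 (adjusted p = 0.0347, and adjusted p = 0.286 with an estimated correlation).

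NRF2 targets were higher after LPS in 12 of 14 genes (13 adjusted over the list alone), with Gclc at 3.70 ± 0.310 (13.0-fold, adjusted p = 4.37e-06), Nqo1 at 2.67, Srxn1 at 2.61 and Gclm at 2.31. Their median was 1.37 (adjusted p = 6.36e-14, and adjusted p = 0.0612 with an estimated correlation). Of 17 lysosomal genes 7 were higher (8 up and 1 down adjusted over the list alone), with Tfeb at 1.14 and the cathepsin Ctsl at 0.96 (adjusted p = 0.00142, and adjusted p = 0.527 with an estimated correlation). Stfa3, a cysteine protease inhibitor gene, was the most raised gene (3.82 ± 0.757, adjusted p = 0.00394). Gsta3 (3.40), Bhlhe41 (3.39), Layn (3.32), Rhob (3.24), Mfge8 (3.19), Akr1c18 (3.09) and Gstp1 (2.99) were also higher.

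Other lists held members that differed after LPS without a shift as a whole. In matrix remodelling Timp1 (-2.83) and Mmp14 (-1.30) were lower and Mmp9 (2.53) and Mmp12 (2.35) higher (adjusted p = 0.721). In macrophage identity Fcgr1 (-2.41), Cx3cr1 (-1.73) and Maf (-1.70) were lower and Cebpa (2.33) higher (adjusted p = 0.919). Prostanoid metabolism had 5 of 17 genes higher and 3 lower (adjusted p = 0.547), cholesterol synthesis 3 of 20 higher and 1 lower (adjusted p = 0.16), and LXR and PPAR lipid handling 4 of 19 higher (adjusted p = 0.0734). LPS sensing had 2 of 17 higher and 4 lower (adjusted p = 0.396). The p53 targets (adjusted p = 0.547), glycolysis (0.533), the cell cycle (0.389) and heat shock (0.58) had not shifted, and Arg1 was at -0.19 (adjusted p = 0.901). Single markers of other cell types differed, among them the osteoclast protease gene Ctsk (2.89 ± 0.599, adjusted p = 0.00514; 2.44 untreated, adjusted p = 0.0467), the eosinophil receptor Ccr3 (-2.17) and the platelet chemokine Ppbp (-2.17). None of the 12 marker lists passed the camera test of limma (lowest adjusted p = 0.0734, B cell markers).

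In all, 3127 genes differed between the genotypes after LPS, 1932 higher and 1195 lower in Hdac3 -/- arrays, and 978 of them by at least 2-fold. Of these calls 61.8% were higher, against 46.8% after cyclic loess scaling. The count was 4440 with array weights, 1685 without -/- LPS 3, 1828 without +/- LPS 3 and 2023 without -/- LPS 1, and calls were lost for lysosome after cyclic loess (0.0665; 0.000824 to 0.0665), for secondary response genes without +/- LPS 1 and without both male arrays (0.107 each; 0.00701 to 0.107) and for alternative activation in 4 of 21 alternatives (0.0128 to 0.11), among them without +/- LPS 2 (0.11) and -/- LPS 2 (0.0672). LXR and PPAR lipid handling gained a call in 4 of 21 (0.0302 to 0.25), with the replicate number as a block (0.0362) and without +/- LPS 2 (0.0359) or -/- LPS 2 (0.0381) among them. LPS sensing gained one after cyclic loess (0.0296; 0.0296 to 0.657) and the cell cycle without both male arrays (0.0462; 0.0462 to 0.947).

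**Figure D2:**
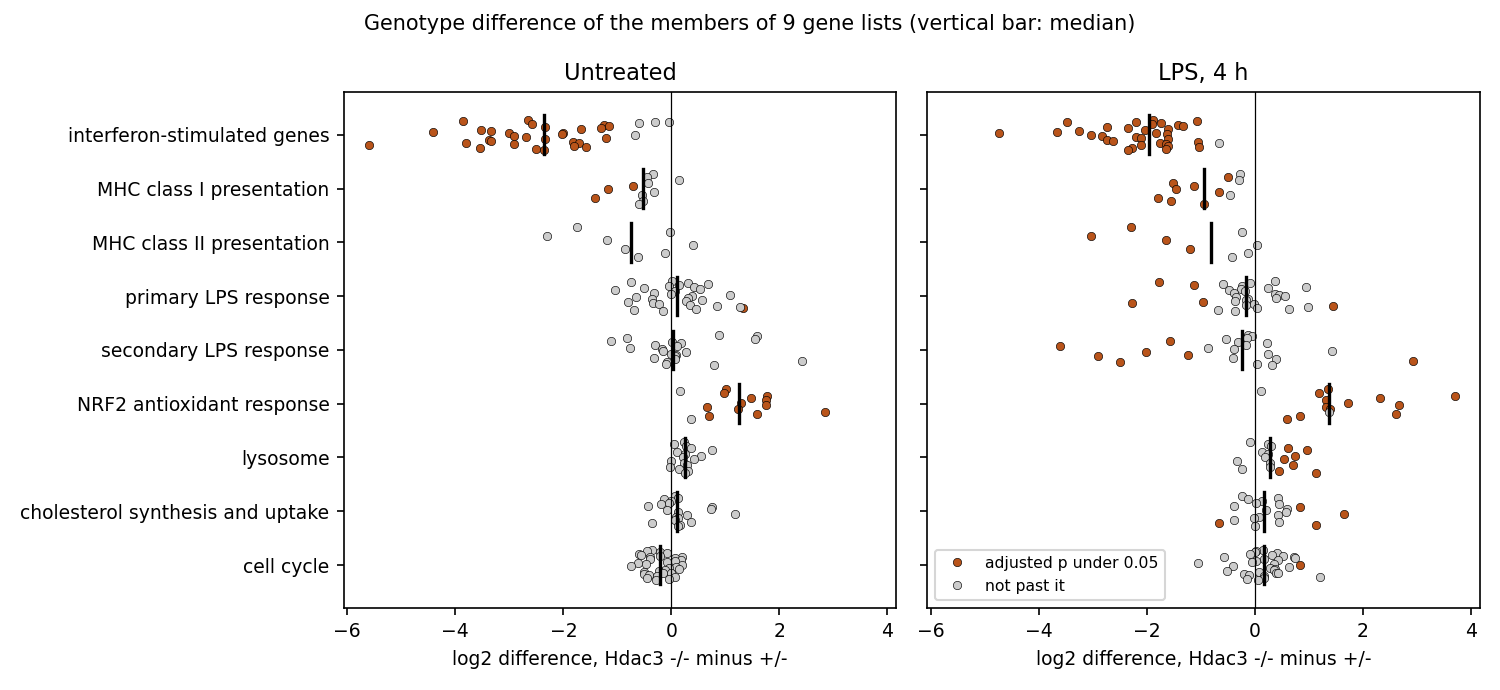
Log2 difference between Hdac3 -/- and +/- arrays of each measured member of 9 gene lists, untreated and after 4 h of LPS, with 1 point per gene, coloured where its adjusted p was under 0.05, and a bar at the list median. The medians of the interferon-stimulated genes lay at -2.35 and -1.97 and those of the NRF2 targets at 1.26 and 1.37.

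The genotype effects before and after LPS share no arrays. They were set against each other to ask whether the difference of unstimulated cells was also there in stimulated ones. Both use the same estimate of each gene's spread, and Hdac3 +/- arrays of a replicate number may be pairs. The number for independent lists is therefore only a reference. Of the genes higher in untreated Hdac3 -/- arrays 191 were also higher after LPS, against 23.54 for independent lists, and of the lower genes 219 were also lower, against 17.26. Only 3 and 0 genes were called in opposite directions by limma, against 14.56 and 27.9. Fcrls, Fgl2, Gsta3, Gstp1, Mfge8 and Akr1c18 were among the 10 most raised or lowered named genes in both. The effects correlated at r = 0.612 (rho = 0.451) across genes, which are not independent replicates.

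The last comparison asked whether loss of Hdac3 changed the LPS response itself, the question in the series title. Averaged over the genotypes LPS induced 565 genes at least 2-fold. Of these 76 (13.5%) responded less in Hdac3 -/- arrays, 10 (1.77%) responded more, and 479 did not pass the test of the difference. These counts depend on the choice and weighting, with 124 reduced for induced genes chosen on Hdac3 +/- arrays alone, 21 for those chosen on Hdac3 -/- arrays alone, and 119 reduced and 19 enhanced with array weights. Tnc rose by 4.66 in Hdac3 +/- arrays and was at 0.29 in Hdac3 -/- arrays (difference -4.36 ± 0.232, adjusted p = 8.63e-07). Edn1 rose by 6.21 and 2.50 (difference -3.70 ± 0.393, adjusted p = 0.000476), Il6 by 6.44 and 3.47 (-2.97 ± 0.412, adjusted p = 0.00298), and Nos2 by 6.70 and 4.30 (-2.40 ± 0.532, adjusted p = 0.0492). Il33 (-3.69), the lipase Lipg (-3.59), Cxcl11 (-3.44), Ifi214 (-3.31), Tnfsf10 (-3.12), Ccnd2 (-3.08) and the GTPase Gbp4 (-3.00) also responded less. The responses of Tnf (-0.29, adjusted p = 0.87), Il1a (0.18) and Il1b (0.31) did not pass the test of a difference.

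Rtp4 rose more in Hdac3 -/- arrays, by 4.59 against 1.10 (difference 3.49 ± 0.365, adjusted p = 0.000474), and so did Cxcl10, by 6.99 against 4.20 (2.78 ± 0.459, adjusted p = 0.00924). Both were lower in untreated Hdac3 -/- arrays and were still lower after LPS (-2.11 and -1.07). Oasl2 (2.05) and H2-M2 (1.76) also rose more. Ints6l (1.99), Aph1b (1.86), Zfp931 (1.85), Cnr2 (1.76), the insulin receptor Insr (1.72) and Impact (1.67) had positive differences too, all 6 with a fall in Hdac3 +/- arrays.

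By list, 4 interferon-stimulated genes responded more (Rtp4, Cxcl10, Oasl2 and Xaf1, 0.87) and 4 less (Cxcl11, Iigp1, Isg20 and Daxx, at -3.44, -2.73, -2.36 and -1.12), or 12 and 7 adjusted over the list alone. Their median was 0.52 (adjusted p = 0.0236, and adjusted p = 0.791 with an estimated correlation). The secondary response genes shifted down, with Edn1, Il6, Nos2 and Il18 (-2.29) past the test (5 adjusted over the list alone; adjusted p = 0.0188, and adjusted p = 0.782 with an estimated correlation). MHC class I presentation shifted down with 0 of 11 genes past limma (2 adjusted over the list alone; adjusted p = 0.0188, and adjusted p = 0.755 with an estimated correlation). NRF2 targets (0 of 14 past limma, 1 adjusted over the list alone) and cell cycle genes (0 of 33, and 0 adjusted over the list alone) shifted up, with medians of 0.30 and 0.47. Both had adjusted p = 0.0236, and adjusted p = 0.788 and 0.791 with an estimated correlation. The primary response list had not shifted (adjusted p = 0.231), with Tnfaip3 (-1.29) past the test. Untreated, Tnfaip3 was 2.52-fold higher in Hdac3 -/- arrays, and after LPS the genotypes differed by 1.03-fold. Mmp13 in matrix remodelling (-2.55; list adjusted p = 0.114) and the cholesterol transporter Stard4 in cholesterol synthesis (0.97; list adjusted p = 0.321) also passed.

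**Figure D3:**
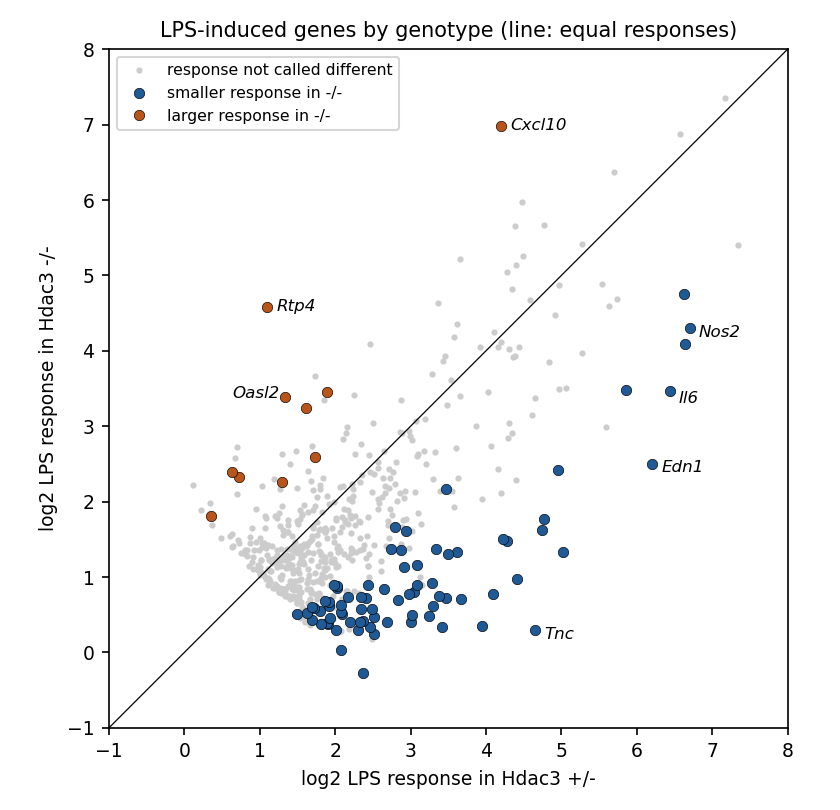
Log2 LPS response in Hdac3 -/- against Hdac3 +/- arrays for the 565 genes induced on average, with 1 point per gene and a line of equal responses. The 76 genes with a smaller response in Hdac3 -/- arrays lie below the line and the 10 with a larger one above it.

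In all, 216 genes passed the test of the difference, 61 positive and 155 negative. The 565 induced genes had a median response of 1.86 in Hdac3 +/- and 1.37 in Hdac3 -/- arrays, and 72.4% of them responded less in the latter. Of 646 genes repressed on average 18 fell less and 1 fell more in Hdac3 -/- arrays. The count of 216 was 592 with array weights, 97 without -/- untreated 1, 113 without -/- LPS 3, 121 without -/- LPS 1, 126 without +/- LPS 3 and 349 without +/- LPS 1, and the 10 larger responses were 5 without +/- LPS 3, -/- untreated 1 or -/- LPS 1 and 6 without +/- LPS 2 or -/- LPS 3. The calls of Zfp931, Il33, Insr, Cnr2, Oasl2 and Ints6l were lost in 17, 14, 12, 11, 11 and 4 of 24 alternatives, with differences of 1.59 to 2.28, -4.17 to -2.79, 1.28 to 2.16, 1.56 to 2.10, 1.58 to 2.35 and 1.76 to 2.35.

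The list calls of the difference also rested on single arrays. For the interferon-stimulated genes (9 of 22 alternatives lost, adjusted p 0.000484 to 0.323) these were +/- untreated 2 (0.105), +/- LPS 1 (0.0835), +/- LPS 2 (0.226), -/- untreated 2 (0.126) and -/- LPS 1 (0.169). For the secondary response genes (4 of 22, 0.000106 to 0.0908) they were +/- untreated 3 (0.0876), +/- LPS 1 (0.0908) and -/- untreated 1 (0.0583), and for MHC class I (4 of 22, 0.00044 to 0.0722) +/- LPS 1 (0.0722) and -/- untreated 1 (0.0526). For the NRF2 targets (9 of 22, 0.000801 to 0.167) they were +/- untreated 2 (0.0834), +/- LPS 3 (0.0953), -/- untreated 2 (0.126) and -/- LPS 3 (0.0923). For the cell cycle (9 of 22, 1.34e-09 to 0.595) they were +/- untreated 1 (0.356), +/- untreated 3 (0.303), +/- LPS 2 (0.595), -/- untreated 3 (0.434) and -/- LPS 3 (0.0923). Without -/- untreated 2 the primary response list was called (0.000719; 0.000719 to 0.538), and without -/- untreated 3 (0.0312) or -/- LPS 3 (0.041) matrix remodelling was (0.0312 to 0.429).

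Marker lists of other cell types had these results with LPS in Hdac3 +/- arrays: dendritic cell markers had adjusted p = 0.0743, megakaryocyte 0.121, stromal and adipocyte 0.172, mast cell and basophil 0.203, erythroid 0.269, B cell 0.331, T and NK cell 0.417, neutrophil 0.641, progenitor 0.878 and osteoclast 0.882. Sex-linked genes set both Hdac3 +/- arrays of replicate 1 apart, with Xist at 3.93 and 3.20 and the Y-linked Uty at 7.62 and 7.22. The other 10 arrays had the pattern of female cells, and the sex-linked list passed in none of the 5 comparisons by limma (adjusted p 0.475 to 0.998). Xist and the Y-linked genes move in opposite directions with sex, so that list test cannot show whether the groups differ in sex.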

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

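The tests of the primary response list and of the heat shock list described here were chosen only after the results were seen, as were the fits with quantile normalization and without both male arrays, and the other tests were planned.

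More genes differed between the genotypes after LPS than before it, 3127 against 531, a ratio of 5.89. The ratio was 4.92 after quantile normalization, which argues against the narrower distribution of the LPS-treated Hdac3 +/- arrays as the whole cause. It was 3.55 at the lowest with 1 deviating array left out, -/- LPS 3, and 8.93 without the male pair of Hdac3 +/- arrays, which argues against either as the whole cause. A difference between the genotypes in how the cultures were grown or stimulated, or in the animals they came from, stays open, because the labels give no batch. The genotype itself is a candidate explanation that stays a hypothesis, since it was found and tested on the same data.

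Interferon-stimulated genes were lower in untreated Hdac3 -/- arrays, with a median of -2.35, which could also mean that the untreated Hdac3 +/- cultures were stimulated. For stimulation by LPS or another NF-kB activator the bound, set after the results were seen, was a primary response median of -0.588 or below. That median was 0.103, with a bootstrap 95% interval over the list's genes, not over cultures, of -0.193 to 0.362. With 4 h of LPS the primary list of Hdac3 +/- arrays rose by a median of 2.09, and the interferon-stimulated genes by 2.57. The values argue against a stimulation like that one. Stimulation at another time or dose was not measured and stays open. Without the male pair of Hdac3 +/- arrays the interferon-stimulated median was -2.43, so those arrays were not its whole cause. Interferon without NF-kB activation, made by the cells or brought in with the culture medium, stays open, as does a lower tonic signal in cells without Hdac3. Ifnb1 stood at a mean log2 signal of 3.85 and 3.90 in the untreated groups, and a signal so low decides nothing.

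NRF2 target genes were higher in Hdac3 -/- arrays, with medians of 1.26 untreated and 1.37 after LPS. The untreated median was 1.30 without the male pair of Hdac3 +/- arrays, so those arrays were not its whole cause. A planned count of called members among the 100 measured genes on either side of Hdac3 gave 0 of 12, but no member of the list lies on chromosome 18 with Hdac3, so the list fixed that count and the bound set beforehand was wrong; a chromosome segment carried along with the Hdac3 allele stays open. For a general protein-damage stress the bound, set after the results were seen, was a rise of the heat shock list by at least 0.628. The list's median was -0.0115, with a bootstrap 95% interval over its genes, not over cultures, of -0.0976 to 0.141. That lies under the bound, but the bound rests on no measured stress response, so such a stress stays open. Oxidative stress of these cultures and direct repression of the targets by Hdac3 may each underlie the pattern and stay open.

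Other splits of the arrays were counted for each comparison. The real split gave the highest count, 1 of 10 splits each, with LPS in Hdac3 +/- arrays (4997, highest other 0), LPS in Hdac3 -/- arrays (1769, highest other 0), genotype untreated (531, highest other 39) and genotype after LPS (3127, highest other 1). With 10 splits the share is never under 0.1, so they are too few for a share under 0.05. In Hdac3 +/- arrays, where the replicate numbers may pair the arrays, 3 other splits also parted all 3 pairs, and each gave 0 genes by limma.

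For the difference of the LPS responses 100 of 200 assignments of the genotypes within each treatment were drawn. As many genes as the real 216 came from 5 of the 100, the real one included, which gives no ground to exclude chance. The 4 others gave 772, 691, 621 and 365 genes. The highest is several times the real count and points to a structure of the samples. All 4 kept the LPS-treated arrays sorted by genotype and mixed only the untreated ones, so the genotype difference after LPS entered the difference of responses. For the 76 induced genes with a smaller response 3 of 100 gave as many, with 121 as the highest other. Here too the others, with 121 and 111, kept the LPS-treated arrays sorted by genotype. Of 5 more assignments that did so 3 gave 69, 65 and 60, and 2 with the LPS labels exchanged gave 4 and 5, so the share does not show whether chance can be excluded for this count either.

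The LPS response differed between the genotypes by a test of the difference itself for the following named genes. It was smaller in Hdac3 -/- arrays for Tnc (-4.36), Edn1 (-3.70), Il33 (-3.69), Lipg (-3.59), Cxcl11 (-3.44), Ifi214 (-3.31), Tnfsf10 (-3.13), Ccnd2 (-3.08), Gbp4 (-3.00) and Il6 (-2.97). It was also smaller for the list members Iigp1 (-2.73), Mmp13 (-2.55), Nos2 (-2.40), Isg20 (-2.36), Il18 (-2.29), Tnfaip3 (-1.29) and Daxx (-1.12). The difference was positive for Rtp4 (3.49), Cxcl10 (2.78), Oasl2 (2.05), Ints6l (1.99), Aph1b (1.87), Zfp931 (1.85), Cnr2 (1.76), H2-M2 (1.76), Insr (1.72), Impact (1.67), Stard4 (0.97) and Xaf1 (0.87). Insr has a probe set beside the one used, and that one had a difference of 0.832 and was not called. The lists that differed had median differences of 0.517 (interferon-stimulated genes), 0.473 (cell cycle), 0.298 (NRF2 targets), -0.257 (secondary response) and -0.348 (MHC class I presentation). None of these 5 lists passed with an estimated correlation in limma, at adjusted p of 0.755 to 0.791, and 0 of them passed without both male arrays.

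Outside the genes tested, probe sets with no symbol or several held signals of their own. Of 6545 such probe sets 85 differed between the untreated genotypes and 337 after LPS, 441 and 130 changed with LPS in Hdac3 +/- and in Hdac3 -/- arrays, and 22 differed in their LPS response.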

How the results depend on the processing

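Quantile normalization, the fit without both male arrays and the fit with a replicate block for each genotype were chosen only after the results were seen, and the other alternatives were chosen before the data were examined. The tests followed were those of the lists, of Hdac3 between the genotypes and of the 10 genes with the largest changes taken in each direction per contrast. Other named list members were not followed. Over the tests followed in all alternatives 5869 values kept their side of the threshold, 183 lost a call, 31 gained one and 1 reversed. A turn of direction was counted only where at least 1 of the values compared was called, and counts of genes are not in this tally. The interferon-stimulated and NRF2 lists were called in both genotype comparisons in every fit that left out an array, with medians of -2.55 to -2.26 and 1.20 to 1.33 untreated and of -2.08 to -1.86 and 1.26 to 1.47 after LPS. After LPS both lists lost their calls with an estimated correlation (adjusted p = 0.0592 and 0.0612). The correlation of the genotype effects ranged from 0.532 to 0.644 over these fits. With 3 arrays per group a log2 change of 1 in the LPS response was found in 46% of simulated genes, and a change of 2 in 90%. The number of arrays thus limits above all the count of genes with small differences. No scaling alternative moved the median of all genes by more than 0.1, but groups of genes moved more. Between the genotypes after LPS, cyclic loess took the median of the Mrpl gene family from 0.521 to 0.355 and of the Gbp family from -2.31 to -2.47. Calls in that comparison were then no longer mostly higher.

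Array weights raised the count with LPS in Hdac3 -/- arrays from 1769 to 4424, between the untreated genotypes from 531 to 1186, and for the difference of responses from 216 to 592, with 119 reduced and 19 enhanced induced genes, and the cause was not tested. The untreated count was 321 with only the 6 arrays compared, which leaves fewer arrays to estimate the spread. A 2-fold minimum left 1792 and 769 genes with LPS, 262 and 978 between the genotypes, and an adjusted p under 0.01 left 2931, 940, 258, 1525 and 73 in the 5 contrasts, as stricter thresholds must. Induced genes chosen on Hdac3 +/- arrays alone gave 124 reduced ones and on Hdac3 -/- arrays alone 21, because a gene that responds less in a genotype is chosen there less readily.

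For the difference of responses 5 lists passed, but 2 with dim genes left out, 2 after cyclic loess, 1 after quantile normalization and 0 without both male arrays, and the cause was not tested. By fry those 5 lists had adjusted p between 0.349 and 0.692. Of lists called by camera in other contrasts, fry passed some and not others. Not passed between the untreated genotypes were, among others, LXR and PPAR lipid handling (adjusted p = 0.12) and MHC class II (0.182). Nor were secondary response genes between the genotypes after LPS (0.0873). With LPS in Hdac3 -/- arrays the cell cycle (0.253) and NRF2 targets (0.0815) did not pass. Between the genotypes after LPS the interferon-stimulated (1.67e-05) and NRF2 (5.74e-05) lists did. With an estimated correlation 0 of 12 and 5 of 13 lists passed with LPS in Hdac3 +/- and Hdac3 -/- arrays, and 3 of 9, 0 of 8 and 0 of 5 in the other contrasts. The interferon-stimulated (-1.97) and NRF2 (1.37) lists after LPS lost their calls there, since the estimate allows for members that move together. Leaving out single arrays gave counts of 1129 (without -/- LPS 1) to 1941 with LPS in Hdac3 -/- arrays, and 266 (without -/- untreated 1) to 606 and 1685 (without -/- LPS 3) to 3495 between the genotypes. For the difference of responses the counts were 97 (without -/- untreated 1) to 349 (without +/- LPS 1), with 2 (without +/- LPS 1) to 5 lists, and 5 (without +/- LPS 3, -/- untreated 1 or -/- LPS 1) to 15 enhanced genes. The median of the cell cycle list between the untreated genotypes went from -0.659 without +/- untreated 2 to 0.0185 without -/- untreated 3, where it reversed, and the cause was not tested.

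With the replicate number as a block the counts were 4864, 1615, 494, 2959 and 158, the LXR and PPAR list after LPS was gained (adjusted p = 0.0362; 0.0302 to 0.25 over its alternatives), and the differences of Zfp931 and Il33 were lost. With a block for each genotype, which suits a pairing of the Hdac3 +/- arrays, the counts were 5478 and 2264 with LPS and 312 for the difference, with 97 reduced and 15 enhanced genes. That fit gained the LXR and PPAR (adjusted p = 0.0192; 0.0192 to 0.496) and MHC class II (adjusted p = 0.0266; 0.0266 to 0.421) lists with LPS in Hdac3 +/- arrays. Calls were followed for the lists, for Hdac3 between the genotypes and for the 10 genes taken in each direction per contrast. Other named list members, such as Nos2 in the difference of responses, were not followed. Among those followed, no other call changed in the fit with the replicate number as a block. Nor did any in that with a block for each genotype, beyond the LXR and PPAR and the MHC class II lists. Genotype contrasts could not be estimated in it, nor the difference of responses from 6 arrays.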

Other observations

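All tests of gene families and of induced genes by list described here were chosen only after the results were seen, and those of the neighbours of Hdac3 and of genes of low level were planned.

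Families of genes with a shared name stem gave groups outside the fixed lists, among 578 families tested with camera. After LPS the interferon-inducible guanylate-binding proteins were lower in Hdac3 -/- arrays in 7 of 8 genes (median -2.31, adjusted p = 1.3e-11, and adjusted p = 0.299 with an estimated correlation), with Gbp9 at -3.65 ± 0.260 (adjusted p = 1.08e-06) and Gbp4 at -3.35 ± 0.191. The Schlafen genes, which act in growth arrest and antiviral defence, were lower in 7 of 9 (median -2.06, adjusted p = 5.98e-08, and adjusted p = 0.288 with an estimated correlation), with Slfn4 at -3.63 ± 0.251. Genes of mitochondrial ribosomes were higher in 18 of 48 of the Mrpl family (median 0.521, adjusted p = 1.67e-09) and 11 of 29 of the Mrps family (median 0.464, adjusted p = 4.85e-06), with Mrpl36 at 1.12 ± 0.148 and Mrps18b at 1.43 ± 0.230. Probe sets named for small nucleolar RNAs, which guide the modification of ribosomal RNA, were higher in 16 of 31 of the Snord family (median 0.652, adjusted p = 6.61e-06). Whether their signal came from the mature small RNAs was not tested. With an estimated correlation these 3 families had adjusted p = 0.89 each. After cyclic loess their medians were 0.355, 0.297 and 0.566, with 12, 6 and 7 genes higher, and no scaling turned the direction of a family named here. The shift was not particular to these 3. Families Rpl, Eif, Polr, Psmd and Tomm were higher after LPS too, with medians of 0.300, 0.378, 0.380, 0.375 and 0.486. The upper quartile of all probe sets was 7.32, 7.19 and 7.15 in the LPS-treated Hdac3 +/- arrays. It was 7.36, 7.29 and 7.44 in the Hdac3 -/- ones, and its part in these shifts was not tested.

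An enhanced response was more frequent among induced interferon-stimulated genes than among other induced genes. Of the 34 induced members 4 (11.8%) were enhanced, against 6 of 531 others (1.13%), with an odds ratio of 11.5 (95% interval 2.27 to 51.7, two-sided Fisher's exact p = 0.00178, adjusted p = 0.0107 over 6 tests). The test rests on 10 enhanced genes, a count of 5 to 15 with 1 array left out. The call of Oasl2, a member among the 4, was lost in several alternatives. The same untreated arrays entered the genotype difference and this response, so genes lower in untreated Hdac3 -/- arrays tend to show larger responses by construction. Of the reduced genes, 4 of 34 members (11.8%) against 72 of 531 others (13.6%) gave a Fisher's exact p = 1 for the share of interferon-stimulated genes (odds ratio 0.85, 0.211 to 2.52), which leaves a difference either way open. Primary response genes were reduced in 1 of 24 (4.17%) and secondary ones in 4 of 16, with Fisher's exact p = 0.231 and 0.252 (adjusted p = 0.503 each).

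A chromosome segment carried along with the Hdac3 allele might change genes beside Hdac3. Of the 100 genes closest to it, 50 measured on either side, 2 were called untreated, Arhgap26 (-0.757, adjusted p = 0.0104) and Ythdc2 (-0.801, adjusted p = 0.048), or 2.0% (exact 95% interval 0.243 to 7.04) against 2.66% of other genes (one-sided Fisher's exact p = 0.748). A p at or above 0.05 had been set beforehand to count against such a segment, which was wrong, because the interval leaves room for a higher share.

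Loss of a repressor could raise above all genes that are low in macrophages. Of genes called between the untreated genotypes 16 were higher in Hdac3 -/- arrays and 12 lower in the lowest 33.3% by level (57.1% higher). The highest 33.3% had 147 higher and 225 lower (39.5%, two-sided Fisher's exact p = 0.0749 against the lowest). The middle 33.3% had 80 and 51 (61.1%), so the share was not greatest in the lowest. Level was the mean signal of the LPS-treated Hdac3 +/- arrays, where all 34 interferon-stimulated genes had risen. Of these, 30 were among the lower genes untreated, so this level does not tell which genes are low in unstimulated cells. Here too a p at or above 0.05 had been set to count against the explanation, which was wrong, because the odds ratio's interval of 0.876 to 4.87 leaves room for a difference.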
